A study of Homo sapiens with 4 samples.

How the data were processed

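Total RNA of Hep3B and HepG2 cells, collected 72 hours after transfection with 100 nM of a miR-493-5p mimic or a negative control mimic, was labelled with Cy3 and hybridised to 4 one-colour Agilent arrays, 1 per group. Groups were taken from the sample titles. Per the file headers, the deposited scanner tables were made by Agilent Feature Extraction 10.7.3.1, and their signal columns are intensity: the processed signal is background-subtracted and spatially detrended by the authors' software and not scaled between arrays. The series matrix holds the authors' processed values in log2, which was checked on the values: differences between the mimic and control columns matched those of log2 processed signal within 0.01 of 1 offset per line (-0.00236 in Hep3B and -5.2e-04 in HepG2) at 100% of bright probes. The column medians were -0.0471, -0.0421, -0.00276 and -0.0141 for Hep3B control, Hep3B mimic, HepG2 control and HepG2 mimic. How the authors scaled the arrays and centred the probes stays unknown, so these values served as an alternative source.

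Each array held 58717 spots of 50599 probes besides 4259 control spots. Control spots and 257 to 362 outlier-flagged spots per array were left out; no spot was saturated. Processed signals were taken to log2, the 75th percentile of the array was subtracted, and spots of a probe were averaged. Replicate spots of a probe, 10 each, had a median SD of 0.0554 to 0.0588 (log2) within an array, which is measurement noise and not biological error. Probe names came from the files: 30004 probes were named through a RefSeq accession, 3112 through a current symbol, 487 through a synonym, and 16996 kept the file's name. Probe coordinates are on hg19. Probes well above background on at least 2 of the 4 arrays were kept (30651), and each of 23548 genes was taken from its brightest kept probe; 4890 genes had more than 1.

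The mimic effect shared by the lines was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with cell line as a block and 1 residual degree of freedom (prior degrees of freedom 1.94), and the line difference with transfection as a block, each at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Within a line, 2 arrays allow a difference and no test, so genes at least 2-fold different were counted. A gene not well above background on 1 side has a bound: the brighter value against the higher of the lowest well-above-background signal of the dim array and the dim value itself, on normalized log2 values, averaged over the arrays of a line for the line difference. No fold is given where both sides were dim. Bounds hold for this background subtraction and scaling only. Expected joint counts are those of independent lists, and intervals of shares are exact (Clopper-Pearson). Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, and described within each line by the percentile of their median among 10000 random lists matched on mean expression in 20 bins. Of 24 lists, 23 could be tested. Probe sequences were searched for 8mer, 7mer-m8, 7mer-A1 and 6mer matches to the miR-493-5p seed, and 7-mers present in at least 20 genes were ranked by a standardised mean difference, with no p. Values were handled with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

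The tests, gene lists, thresholds and alternatives were fixed before the data were examined, except where stated as chosen later. Named genes followed a rule on raw log2 differences, dim readings included, also fixed then: all reported miR-493-5p targets; the 12 largest joint increases and decreases among genes at least 2-fold different the same way in both lines; the 5 largest increases and decreases of each line among genes well above background on at least 1 of its arrays; up to 4 members per list with the largest mean difference; the 10 largest line differences each way among genes past the threshold; and the 10 largest decreases among genes with an 8mer. Differences at the other probes of named genes were added after the main values had been seen. Names that are only a locus or accession number, and sex-linked marker genes, were left out of the choice.

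The fits were tested on simulated arrays with 100 genes planted at a 2-fold and 100 at an 8-fold mimic effect. With gene variances set to limma's posterior values, 5 of the 2-fold and 98 of the 8-fold genes were called, and 24 unchanged genes, 18.9% of all calls. Because of those false calls a second noise model, with variances drawn from the fitted prior, was added after the first outcome had been seen; it gave 0 and 0 calls and 0 unchanged genes. The number of calls that this design allows thus depends on the noise model. For the line difference, 0 of 100 genes planted at a 2-fold and 0 of 100 at an 8-fold difference were called, so calls depend on how many genes differ. With 4000 genes planted at an 8-fold and 4000 at a 64-fold line difference, 96.7% and 99.2% were called and 3.04% of calls were unchanged genes. The line simulations used only variances drawn from the prior, and this one planted no difference under 8-fold. Its share of false calls may therefore not hold for the real line calls. A list of 40 genes lowered by 0.3 had a camera p of 6.8e-12 with the preset and 0.0783 with an estimated correlation. A simulated lowering by 0.2 of the genes with ATGTACA put that word at rank 1 of 14865.

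Alternatives, each changing 1 choice, were normexp background correction with an offset of 50, quantile or median scaling, all 4 arrays or no filter for dim probes, the mean of all kept probes, the authors' values, an intensity trend in eBayes, no block, an adjusted p under 0.1, a 1.5-fold rule, the other set tests and, chosen after seeing the files, filters by line and an adjustment for probe GC content. Tests on 3' UTRs were left out because no 3' UTR sequences were available.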

Results

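Gene expression was measured in Hep3B and HepG2, 2 human liver cancer cell lines, 72 hours after transfection with 100 nM of a miR-493-5p mimic or of a negative control microRNA mimic. A mimic is a short double-stranded RNA that raises the level of a microRNA in the cell. Each of the 4 combinations of line and transfection was hybridised to 1 one-colour Agilent array, so no group had a replicate, and the number of arrays limits the precision of every value. On the arrays of Hep3B control, Hep3B mimic, HepG2 control and HepG2 mimic, 57.3%, 55.6%, 59.5% and 57.7% of 50599 probes were well above background. The 75th percentile of the signal was 323, 342, 298 and 285 in the same order. Of the probes, 30651 were kept, and they measured 23548 genes. Across kept genes, which are not independent replicates, the arrays of mimic and control correlated at r = 0.980 in Hep3B and 0.990 in HepG2, and arrays of different lines at 0.831 to 0.847. All 4 arrays were on 1 slide with 1 scan, the lines held separate positions on it, and the mimic array followed its control in both lines.

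The first comparison asked which genes differed between mimic and control in both lines. ANXA1, which encodes the phospholipid-binding protein annexin A1, was 18.3-fold higher with the mimic in Hep3B and 17.9-fold higher in HepG2. The keratin gene KRT80 was 6.25-fold and 8.41-fold higher. Lower in both lines were CHRNA4, a nicotinic acetylcholine receptor subunit, by a log2 difference of -2.34 in Hep3B and -1.20 in HepG2, and JPT1, by -1.95 and -1.23. KNG1, which encodes the plasma protein kininogen, differed by -1.74 and -1.29, and the long non-coding RNA gene HLMR1 by -2.34 and -1.24, or by -2.42 and -0.61 at a second HLMR1 probe. No single gene passed limma's test of the mean of the lines, with 0 higher and 0 lower of 23548 at an adjusted p under 0.05. The smallest adjusted p was 0.562, and 1973 genes had an unadjusted p under 0.05 against 1177.4 expected by chance. The values below are therefore differences of single arrays, with no call for any single gene.

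Other genes at least 2-fold different the same way in both lines, named by their raw log2 differences, were not well above background on 1 array or both arrays of a line. Where 1 array was dim only a bound is given, and bounds do not rank genes. COL1A1, a fibrillar collagen chain, was at least 23.3-fold higher with the mimic in Hep3B and at least 1.38-fold higher in HepG2. GFPT2, an enzyme of hexosamine synthesis, was at least 31.9-fold and at least 2.5-fold higher. The tetraspanin gene CD9 was at least 5.54-fold higher in Hep3B and 5.30-fold higher in HepG2. MTMR11 was at least 8.5-fold higher in Hep3B and 6.27-fold higher in HepG2, and the semaphorin gene SEMA3C 5.94-fold and at least 2.52-fold higher. TILAM, MN1, CPEB2, CXCR2P1 and B4GALT6 were also higher, with bounds of at least 1.32-fold to at least 9.64-fold. On the lower side, GCGR, the glucagon receptor, was at least 4.61-fold lower in Hep3B and at least 5.06-fold lower in HepG2. FNDC5 was 7.14-fold and at least 1.83-fold lower, and ARHGAP44 at least 6.75-fold and 2.35-fold lower. FAM81A was at least 1.41-fold and at least 1.04-fold lower. MYCN, a transcription factor of the MYC family, was 15.2-fold lower in Hep3B and was not well above background on either HepG2 array. NAV2-AS4, FAM99A and HAL, which encodes histidine ammonia-lyase, were 3.93-fold, 2.69-fold and 4.12-fold lower in Hep3B and likewise not well above background in HepG2.

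Taking all 23548 genes, 138 were at least 2-fold higher with the mimic in both lines, against 29.5 expected from independent lists, and 48 were at least 2-fold lower in both, against 13.1 expected. Another 97 genes were at least 2-fold different in opposite directions, against 42.8 expected. The share moving the same way was 65.7% of 283 genes (exact 95% interval 59.9% to 71.2%). Among 18967 genes well above background on all 4 arrays, 68 were higher in both, 13 lower in both and 11 opposite, a share of 88.0% (79.6% to 93.9%). These intervals treat genes as independent, which genes are not. Across all genes the differences of the lines had a Pearson correlation of 0.194 and a Spearman correlation of 0.285. The Pearson correlation was 0.335 among probes well above background on all 4 arrays and 0.0811 with no filter on dim probes. After normexp background correction it was 0.326, with 23 genes higher in both lines, 3 lower in both and 7 opposite.

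**Figure D1:**
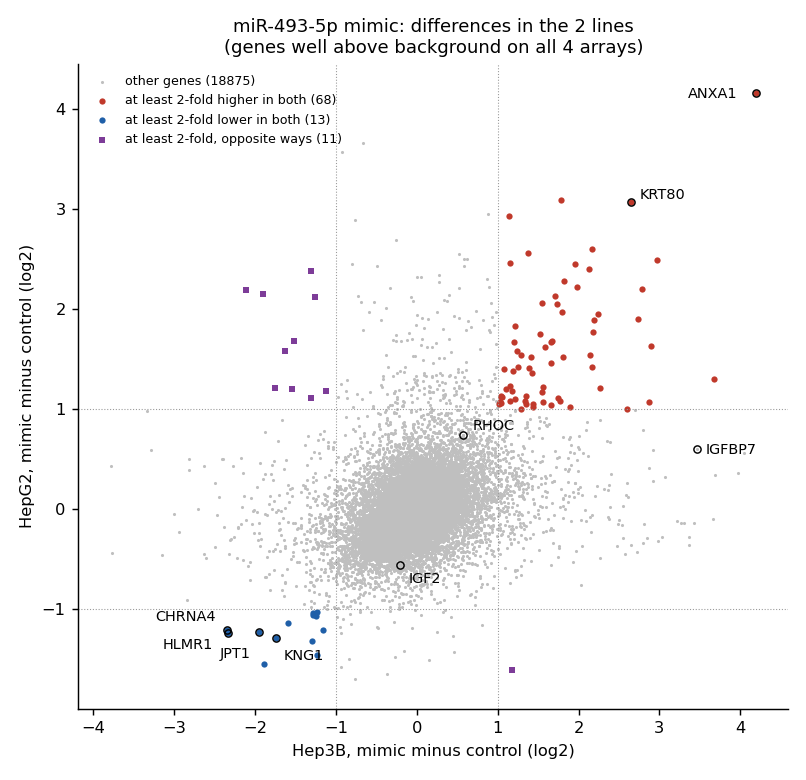
Each point is a gene well above background on all 4 arrays, with its mimic minus control difference (log2) in Hep3B on the x axis and in HepG2 on the y axis; dotted lines mark a 2-fold difference. Coloured points show the 68 genes higher in both lines, the 13 lower in both and the 11 that went opposite ways, and ANXA1 lies farthest to the upper right at 4.20 and 4.16.

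The second set of genes were 7 reported targets of miR-493-5p, listed from general knowledge before the data were examined. IGF2, a fetal growth factor, was measured by a very bright probe on chromosome 11 (hg19 positions 2150394 to 2150453) that differed by -0.21 in Hep3B and -0.56 in HepG2, with a mean of -0.38 (SE 0.17). A dimmer IGF2 probe differed by -1.05 and -0.58, so the probes disagreed in size in Hep3B and shared their direction. MAP2K7, a kinase that activates JNK, differed by -0.14 and -0.21, and E2F1, a transcription factor of the cell cycle, by -0.03 and -0.05. IGF1R, the receptor of insulin-like growth factors, was higher by 0.36 in Hep3B and differed by -0.48 in HepG2, and the Wnt receptor gene FZD4 by +0.51 and -0.73. RHOC was higher by 0.58 and 0.74. GOLM1, a Golgi membrane protein, differed by -0.35 in Hep3B; the same probe was not well above background in HepG2, and a second probe, well above background on all 4 arrays, differed by +0.01 and +0.10. Of the 6 genes well above background in both lines, 3 were lower in both, 1 was higher in both and 2 went opposite ways. None passed over all genes or adjusted over the list alone, where the smallest adjusted p from limma was 0.133. Camera gave the list an adjusted p of 0.915.

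**Figure D2:**
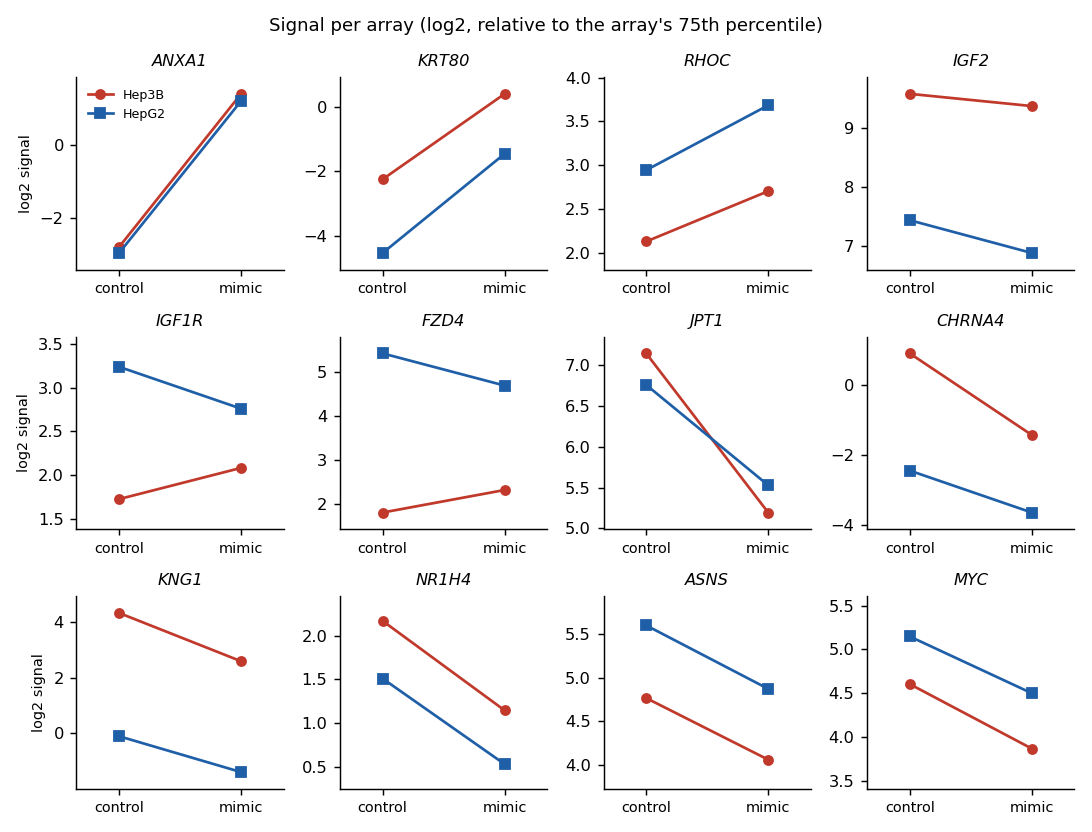
Each panel shows 1 gene, with the log2 signal relative to the array's 75th percentile on the y axis for the control and mimic array of Hep3B (red circles) and HepG2 (blue squares), 1 array per point. ANXA1 and KRT80 lie higher on the mimic array of both cell lines, whereas the lines of IGF1R and FZD4 have opposite slopes.

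Within Hep3B alone, 1012 genes were at least 2-fold higher and 1021 at least 2-fold lower with the mimic, a difference of 2 arrays with no test. The genes named here were picked by raw differences that include dim readings, so their bounds do not rank them. TAS1R3, a taste receptor subunit, was at least 81.9-fold lower, and LHX2, TSPEAR, the chemokine gene CCL11 and EMP1 at least 17.1-, 14.5-, 10.1- and 9.16-fold lower. Besides COL1A1, GFPT2 and CXCR2P1, given above, the collagen receptor gene DDR2 and the homeobox gene BSX were at least 30.1-fold and at least 23.4-fold higher. Each of these genes was not well above background on 1 of the Hep3B arrays. Measured on both Hep3B arrays, MYCN (15.2-fold lower) and ANXA1 (18.3-fold higher) exceeded some of these bounds.

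Within HepG2, 687 genes were at least 2-fold higher and 303 at least 2-fold lower. These counts were 185 and 14 after normexp background correction and 292 and 44 among probes well above background on all 4 arrays, and in Hep3B they were 317 and 254, and 468 and 380. Picked in the same way, CSRNP3, KCNQ1, PNMA6A, NRSN1 and RPL39L were at least 15.6-, 7.96-, 7.16-, 2.65- and 2.57-fold lower. Of the other CSRNP3 probes, 1 was at least 1.40-fold higher in HepG2 and 1 was not well above background on either HepG2 array. Besides ANXA1, S100A3, a calcium-binding S100 protein, was 14.2-fold higher, and NAV3, TILAM and B4GALT6 were at least 6.82-, 6.74- and 4.73-fold higher. KRT80, measured on both arrays at 8.41-fold, exceeded the last 3 bounds. A second NAV3 probe showed no such difference (0.00). The mimic effect differed between the lines by at least 2-fold at 2509 genes. That count was 595 after normexp background correction and 921 among probes well above background on all 4 arrays. With 1 array per group the difference in effect could not be tested.

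Gene lists fixed before the data were examined described the shared mimic effect at the level of pathways. Camera with a preset correlation called 8 of 23 lists, 7 lower and 1 higher with the mimic. None of the 8 calls held with an estimated correlation (adjusted p = 0.859 for each), and fry called none (smallest adjusted p = 0.335). No member of any list passed over all genes or adjusted over the list alone, so the members named next are given with their values. Counts of list members and medians include genes that were not well above background on some arrays. Percentiles among random lists reflect the spread between genes on the same arrays. They do not measure the spread between cultures, and members of a list can move together, so they are descriptions.

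Genes of the unfolded protein and integrated stress response, which cells switch on under protein folding or amino acid stress, fell as a group (adjusted p = 9.6e-04; adjusted p = 0.859 with an estimated correlation). Of 25 measured, 17 were lower in both lines and 2 higher in both. PHGDH, the first enzyme of serine synthesis, differed by -1.27 in Hep3B and -0.82 in HepG2, and ASNS, asparagine synthetase, by -0.70 and -0.72. DDIT4, an inhibitor of mTORC1, differed by -1.30 and -0.39, whereas VLDLR was higher by 0.92 and 0.20. The median of the list was -0.49 in Hep3B and -0.24 in HepG2, below all 10000 expression-matched random lists in each line.

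Secreted and metabolic genes of hepatocytes also fell as a group (adjusted p = 9.6e-04; adjusted p = 0.859 with an estimated correlation), with 23 of 40 lower in both lines and 3 higher in both. The fibrinogen chain FGB differed by -1.28 and -0.93, the retinol carrier RBP4 by -1.37 and -0.63, and CPS1, the entry enzyme of the urea cycle, by -1.73 and -0.34. G6PC1, which releases glucose from glucose 6-phosphate, differed by -0.83 in HepG2 and was not well above background in Hep3B. The median was -0.45 in Hep3B, below all random lists, and -0.15 in HepG2, at the 0.29 percentile, or the 3.27 percentile after normexp background correction. Transcription factors of hepatocytes were called lower as well (adjusted p = 0.0353; adjusted p = 0.859 with an estimated correlation), with 10 of 17 lower in both lines and 3 higher in both. The bile acid receptor NR1H4 differed by -1.02 and -0.98, RXRA by -0.57 and -0.50, and CEBPA by -1.06 and -0.28. PPARA differed by -0.67 and -0.68 at its brightest probe and by +0.32 and -0.03 at a second one, also well above background on all 4 arrays. The median of these transcription factors lay at percentile 18.9 in Hep3B and 0.27 in HepG2.

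Genes of DNA replication fell as a group (adjusted p = 8.7e-04; adjusted p = 0.859 with an estimated correlation), with 32 of 41 lower in both lines. The median was -0.22 in Hep3B and -0.20 in HepG2, at percentiles 0.65 and 0.01. RFC5, a clamp loader subunit, differed by -0.89 and -0.61, CCNE1, cyclin E1, by -0.73 and -0.65, and RRM2, a ribonucleotide reductase subunit, by -0.80 and -0.39. E2F2 was higher by 0.59 and 0.93. Genes of mitosis fell too (adjusted p = 9.8e-04; adjusted p = 0.859 with an estimated correlation), with 29 of 35 lower in both lines and medians of -0.23 and -0.19, at percentiles 0.50 and 0.03. The mitotic kinases AURKA and PLK1 differed by -0.59 and -0.55 in Hep3B and by -0.41 and -0.34 in HepG2. CKS2 differed by -0.74 and -0.13, and CCNA2, cyclin A2, by -0.46 and -0.23.

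Cytosolic ribosomal protein genes were called lower (adjusted p = 8.7e-04; adjusted p = 0.859 with an estimated correlation), with 32 of 38 lower in both lines. Their medians were -0.30 in Hep3B and -0.09 in HepG2, at percentiles 0.71 and 10.3 of random lists of like brightness. Those random lists were themselves lower with the mimic, with typical medians of -0.19 and -0.064. After quantile normalization the ribosomal medians were -0.066 and -0.042, at percentiles 7.44 and 4.4. RPL7A differed by -0.70 and -0.30 and RPL14 by -0.54 and -0.16. Replication-dependent histone genes were called lower (adjusted p = 0.0353; adjusted p = 0.859 with an estimated correlation), with 14 of 25 lower in both lines and medians at percentiles 0.86 and 21.6. The HepG2 median lay at percentile 84.1 with the mean of all probes of a gene. H1-5 differed by -0.26 and -0.70 and H2BC21 by -0.59 and -0.09. The calls of the hepatocyte transcription factors, the histones and the ribosomal proteins were lost after quantile normalization, and that of the histones also with the mean of all probes of a gene. Over the lines, quantile normalization took the median of the ribosomal proteins from -0.19 to -0.054, that of the transcription factors from -0.15 to -0.16 and that of the histones from -0.15 to -0.12, so only the ribosomal median shrank much.

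Interferon-stimulated genes were the list called higher (adjusted p = 0.0371; adjusted p = 0.859 with an estimated correlation), with 10 of 26 higher in both lines and 2 lower in both. The median was 0.34 in HepG2, above all random lists. In Hep3B it was -0.01, at percentile 67.2, and was 0.06 after quantile normalization, 0.05 after median scaling and 0.16, at percentile 98.1, among probes well above background on all 4 arrays. It was also 0.10 with no filter on dim probes, -0.034 after normexp background correction and -0.15, at percentile 11.2, with the mean of all probes of a gene, so its direction was not settled. OAS1, an antiviral sensor of double-stranded RNA, was higher by 2.01 in HepG2 and was not well above background in Hep3B. IRF9 was higher by 1.11 in Hep3B and 0.79 in HepG2, and IFIT1 by 1.09 and 0.64, whereas IFIT3 was at least 1.55-fold lower in Hep3B and differed by -0.09 in HepG2. The call was lost after quantile normalization, with no filter on dim probes and with the mean of all probes of a gene.

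**Figure D3:**
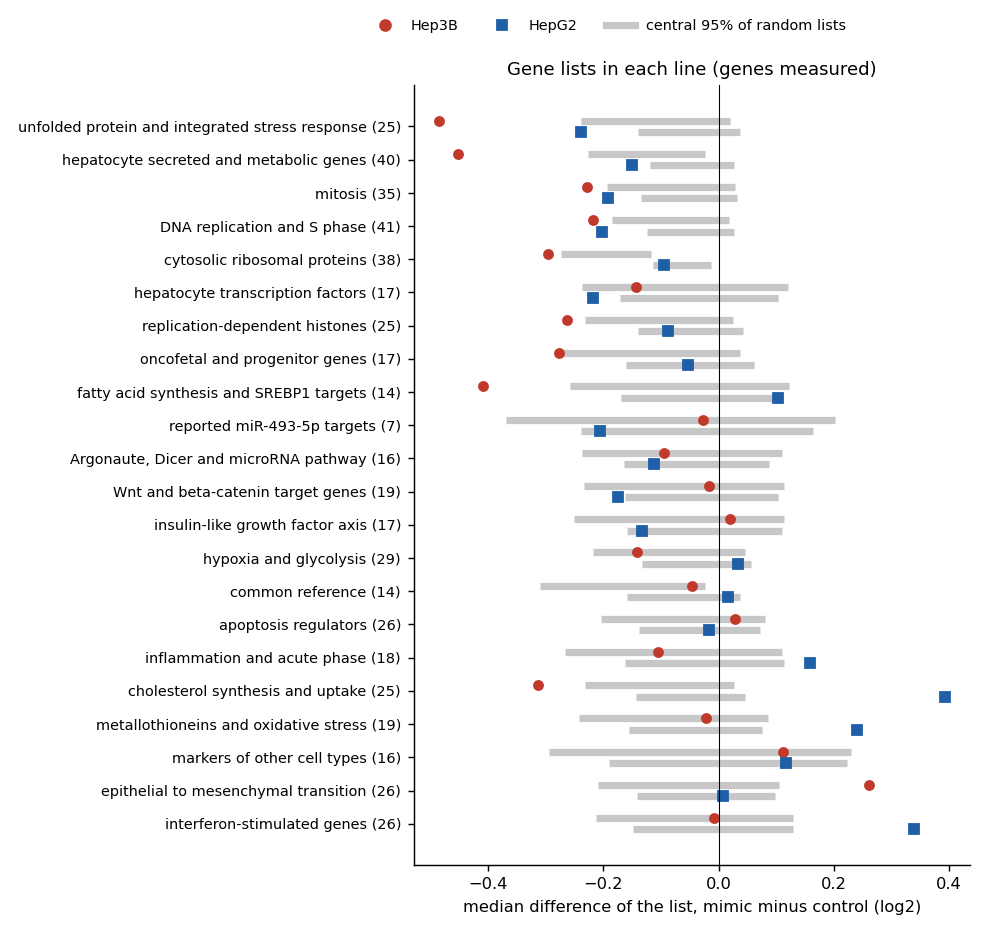
The x axis gives the median mimic minus control difference (log2) of 22 fixed gene lists, with the number of genes measured in brackets, in Hep3B (red circles) and HepG2 (blue squares); grey bars span the central 95% of 10000 expression-matched random lists. The unfolded protein list lies left of both bars at -0.49 and -0.24, and the cholesterol list lies left of its Hep3B bar at -0.31 and right of its HepG2 bar at 0.39.

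Some lists differed between the lines. Genes of cholesterol synthesis and uptake, controlled by SREBP2, had a median of -0.31 in Hep3B, at percentile 0.06, and of 0.39 in HepG2, above all random lists. Of 25 measured, 22 were lower in Hep3B and 23 were higher in HepG2. STARD4 differed by -0.16 and +0.88, and IDI1 by -0.11 and +0.65, while SC5D was higher in both, by 0.69 and 0.63, as was PMVK, by 0.36 and 0.21. Genes of fatty acid synthesis had medians of -0.41 and 0.10, at percentiles 0.04 and 97.8. Of 14 measured, 12 were lower in Hep3B and 9 higher in HepG2, with 9 opposite and 4 lower in both. The HepG2 median was 0.038, at percentile 97.8, after median scaling, 0.049, at percentile 91.2, with no filter on dim probes, 0.12, at percentile 97.7, after quantile normalization and 0.16, at percentile 99.5, among probes well above background on all 4 arrays. GPAM, the first enzyme of glycerolipid synthesis, differed by -1.82 and -0.64, FASN, fatty acid synthase, by -1.13 and -0.21, and ACACA, acetyl-CoA carboxylase, by -0.56 and -0.13. ME1 was higher by 0.95 in Hep3B and was not well above background in HepG2. Camera did not call either list for the mean of the lines (adjusted p = 0.398 and 0.498), and the difference between the lines was not tested.

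**Figure D4:**
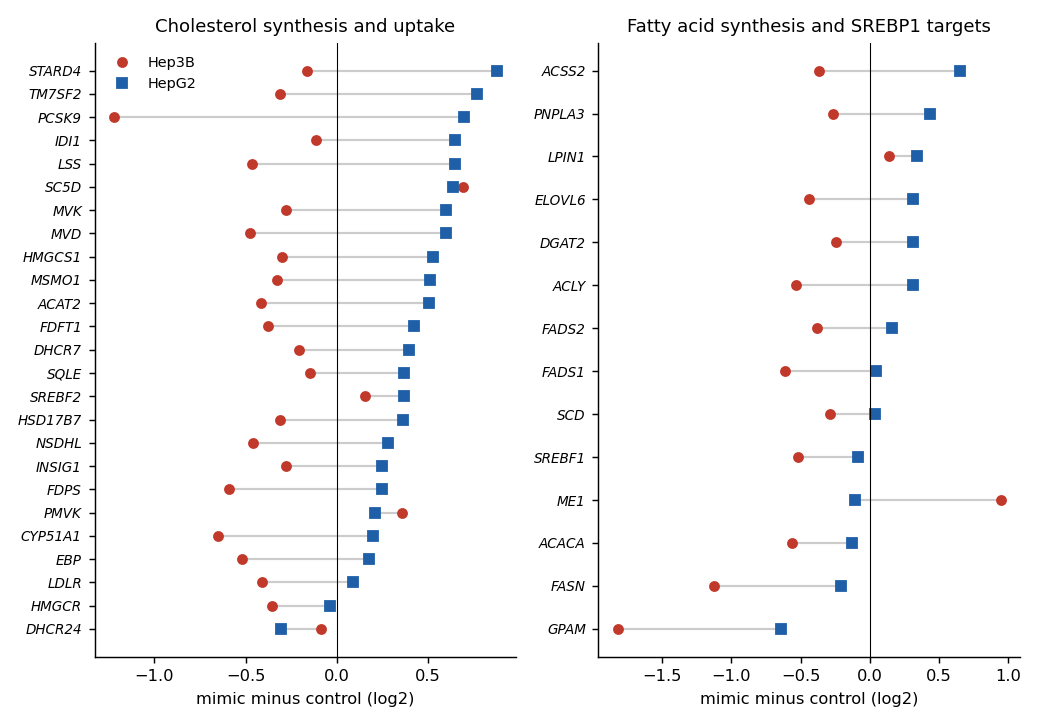
Each line of the plot is a gene of the cholesterol list (left) or the fatty acid list (right), with its mimic minus control difference (log2) on the x axis in Hep3B (red circle) and HepG2 (blue square), joined by a grey bar. In the cholesterol list 22 of 25 genes lie below 0 in Hep3B and 23 of 25 above 0 in HepG2.

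Genes of the epithelial to mesenchymal transition had a median of 0.26 in Hep3B, at percentile 99.98, and of 0.01 in HepG2, at percentile 72.1, which was -0.06 after median scaling and 0.10, at percentile 98.1, among probes well above background on all 4 arrays. The actin-binding protein gene TAGLN was higher by 2.10 and 0.87, whereas the transcription factor SNAI1 differed by -1.28 and -0.38. Metallothionein and oxidative stress genes had medians of -0.02 and 0.24, at percentiles 78.3 and 99.99, and the Hep3B median was 0.04 after median scaling. The metallothioneins MT1M, MT1G, MT1E and MT1H were higher by 2.35, 2.58, 1.90 and 1.03 in Hep3B and by 0.68, 0.15, 0.73 and 0.49 in HepG2; a second MT1E probe was higher by 0.82 and 0.55. Inflammation and acute phase genes had medians of -0.11 and 0.16, at percentiles 40.6 and 99.3. Among the 12 members with probes well above background on all 4 arrays the medians were -0.85, below all random lists, and 0.0091, at percentile 81.3, and with no filter on dim probes the Hep3B median was 0.047. The iron hormone gene HAMP differed by -0.94 and -1.58 and the acute phase gene ORM1 by -1.61 and -0.60. Wnt target genes had medians of -0.02 and -0.17, at percentiles 75.3 and 1.57, and the Hep3B median was 0.09 after quantile normalization and 0.04 after median scaling. After normexp background correction the HepG2 median was -0.061, at percentile 23.7. MYC differed by -0.74 and -0.65 and GLUL by -0.32 and -0.55. Camera called none of these lists (adjusted p = 0.219, 0.159, 0.959 and 0.894 in this order), though with normexp background correction or with probes well above background on all 4 arrays it called the epithelial to mesenchymal list higher (adjusted p = 0.0375 and 0.0296). The latter filter also gave a call, lower with the mimic, to 1 list that is not described here.

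The other lists described were not called either. In the insulin-like growth factor axis (adjusted p = 0.933) the median was -0.06 and the mean 0.05; IGFBP7 was higher by 3.47 in Hep3B and 0.61 in HepG2, and IGFBP1, a liver-secreted binding protein, differed by -2.23 and -0.48. Only 2 of 7 genes of the imprinted DLK1-DIO3 locus, which holds the miR-493 gene, were measured, too few for a set test; DLK1 differed by -0.87 and -0.38 and MEG3 by -0.14 and +0.09, or by +0.38 and +0.42 in HepG2 at 2 other probes. Among oncofetal genes (adjusted p = 0.311), AFP, alpha-fetoprotein, differed by -1.63 and +0.01 and KRT19 by +0.34 and +2.09. Hypoxia and glycolysis genes (adjusted p = 0.486) had a median of -0.01 and a mean of 0.07; PFKP was higher by 1.11 and 1.21. Among apoptosis regulators (adjusted p = 0.398), BIK was higher by 2.27 and 0.90 and BIRC3 by 1.07 and 1.40. The microRNA pathway had an adjusted p of 0.341, with XPO5 at -0.63 and -0.40. Common reference genes had an adjusted p of 0.855 and a median of -0.03, which was 0.063 after quantile normalization, and GAPDH differed by -0.76 in Hep3B and +0.01 in HepG2. Markers of other cell types had an adjusted p of 0.4999 by camera. Apart from COL1A1, LUM was higher by 2.82 in Hep3B, and COL1A2 by 0.84. GFAP differed by -0.85 in HepG2 and was not well above background in Hep3B.

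The cell lines were compared as HepG2 minus Hep3B over both transfections. HepG2 was higher at 5116 genes and Hep3B at 4554 of 23548 by limma, and 3769 and 3343 of these differed by at least 2-fold. Higher in Hep3B were GC, the vitamin D-binding protein, at least 5560-fold, the cell cycle inhibitor gene CDKN1C, at least 5849-fold, and VIM, vimentin, at least 6418-fold, none of them well above background in HepG2. H19, an imprinted long non-coding RNA, was at least 6769-fold higher at its brightest probe. UCHL1, CTNND2, CXCL1, CD81, PGAP4 and TM4SF4 were at least 456-fold to at least 1074-fold higher. Second probes of H19 and CD81, well above background on all 4 arrays, gave 2184-fold and 92.3-fold, so the bounds of these genes hold for their brightest probes only. A second CXCL1 probe, dim on 1 HepG2 array, gave at least 74.1-fold. Higher in HepG2 and not well above background in Hep3B were SAT2, FGF13 and the kinase gene RPS6KA3, at least 1024-, 773- and 750-fold, and SLC6A4, the serotonin transporter, at least 537-fold. COL21A1, TNS4, CADM1, BOK-AS1, DSCR8 and TDRD1 were at least 177-fold to at least 405-fold higher. A second TDRD1 probe, dim on 1 Hep3B array, gave at least 44.2-fold. Adjusted p of these 20 genes ranged from 0.00442 to 0.0187.

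Camera called 10 of 23 lists between the lines, 7 higher in HepG2 and 3 higher in Hep3B, with adjusted p from 5.8e-05 to 0.00598. None held with an estimated correlation (adjusted p = 0.732 or more), while fry called the Wnt targets (adjusted p = 0.0240) and 1 list that is not described here. Metallothionein and oxidative stress genes were higher in HepG2 at 16 of 19 and at none lower; MT1G differed by 7.78 and MT1M by 6.92. Wnt target genes were higher in HepG2 at 12 of 19, with FZD4 at 3.00, and higher in Hep3B at 2, DKK1 at -6.0 and LEF1, which was not well above background in HepG2. Interferon-stimulated genes were higher in HepG2 at 16 of 26, with IFIT1 at 4.04, and hypoxia and glycolysis genes at 17 of 29, with PFKP at 4.10. Stress response genes were higher at 12 of 25, with PHGDH at 2.33, and ribosomal protein genes at 9 of 38, with RPL14 at 1.06. Over all 23548 genes, 5116 were higher in HepG2, a share near that of the ribosomal protein genes, and 4554 were higher in Hep3B. In Hep3B, 14 of 41 DNA replication genes, 17 of 35 mitosis genes and 8 of 25 histone genes were higher; CCNE1 differed by -0.64 and H1-5 by -3.12. Adjusted over the list alone, the numbers that passed were 16 metallothionein and oxidative stress genes, 18 Wnt targets, 21 interferon-stimulated, 23 hypoxia, 19 stress response, 0 ribosomal, 19 replication, 21 mitosis and 8 histone genes.

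The last comparison asked whether genes matching the seed of miR-493-5p differed from other genes. No 3' UTR sequences were at hand, so the match was sought in the 60-base probe sequences of each gene, a search chosen after the files had been seen that covers only the part of each transcript a probe holds. The 57 genes with an 8mer match had a median of -0.17 over the lines, at percentile 0.16 of random lists. In the single lines they were less extreme, at percentile 5.89 in Hep3B and 5.7 in HepG2. The 120 genes with a 7mer-m8 match had a median of -0.10, at percentile 0.87 (21.1 in Hep3B and 1.19 in HepG2). The 129 with a 7mer-A1 match had a median of -0.08, at percentile 8.16 (4.2 in Hep3B and 3.21 in HepG2). The 425 genes with a 6mer match had a median of -0.03, at percentile 73.0, a mean of 0.01 and camera's direction up. Together the 306 genes with an 8mer or 7mer match had a median of -0.12 in Hep3B and -0.09 in HepG2, at percentiles 0.53 and 0.01. Camera did not call the 8mer genes after adjustment (adjusted p = 0.208; adjusted p = 0.644 with an estimated correlation), nor the 306 together (adjusted p = 0.334). Among 8mer genes, MARS1, a methionyl-tRNA synthetase, differed by -0.92 and -0.72, NDST1, an enzyme of heparan sulfate synthesis, by -0.70 and -0.76, and the prostaglandin receptor gene PTGER3 by -0.70 and -0.54. ZFP3 differed by -2.94 and -0.22, TANGO6 by -0.84 and -0.24, MND1 by -0.69 and -0.38, CCDC59 by -0.64 and -0.37, and CARD9 by -1.41 and +0.24, or -0.11 and -0.03 at a second CARD9 probe. LIPM was at least 1.34-fold lower in Hep3B and CAPN13 at least 1.72-fold lower in HepG2. The 7-mer ATGTACA, present in 177 genes, ranked 838 of 14865 from the most negative score (5.64%), with a mean difference of -0.07 (SE 0.04). The rank was 0.231% among probes well above background on all 4 arrays, 0.888% after normexp background correction, 2.44% with the mean of all probes, 3.51% after adjustment for GC content and 6.81% with no filter on dim probes.

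**Figure D5:**
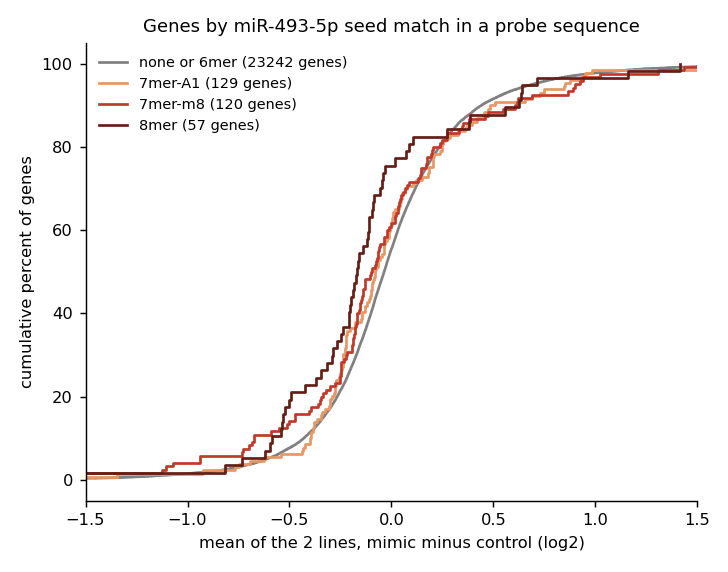
Cumulative percent of genes (y axis) by the mean mimic minus control difference of the lines (log2, x axis), for genes with an 8mer (57), 7mer-m8 (120) or 7mer-A1 (129) match to miR-493-5p in a probe sequence and for all others; each step is 1 gene. The 8mer curve lies to the left of the curve of the other genes, with a median of -0.17.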

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

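The tests of explanations below were written down before their outcomes were seen, the choice of left-out spots and the lower brightness limit for the IGF2 test were set after values had been seen, and none of the differences between the lines was tested, since each group had 1 array.

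Genes of cholesterol synthesis and uptake went opposite ways in the lines, with a median of -0.31 in Hep3B and 0.39 in HepG2. Genes of fatty acid synthesis had medians of -0.41 and 0.10, with 9 of 14 genes opposite and 4 lower in both lines. The HepG2 median ranged from 0.038 after median scaling to 0.16 among probes well above background on all 4 arrays. The raw differences of EMP1 were -5.35 in Hep3B and 3.37 in HepG2, and those of NRSN1 4.43 and -3.35. EMP1 in Hep3B and NRSN1 in both lines were not well above background on 1 array, so these sizes were not measured. EMP1 was at least 9.16-fold lower in Hep3B, and NRSN1 at least 5.26-fold higher in Hep3B and at least 2.65-fold lower in HepG2. These bounds hold for the main processing only. After normexp background correction the EMP1 difference in Hep3B was -1.76 (log2), smaller in size than its bound. In all, 97 genes were at least 2-fold different in opposite directions, 11 of them among genes well above background on all 4 arrays.

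Spots left out for an outlier flag were not used in any comparison, and in the authors' values 5 of them differed widely between the mimic and the control array of a line. OPRK1 was higher by 13.9 (log2) in HepG2. In Hep3B, OR6C70 was higher by 5.13, OR4F6 by 7.21 and LOC93429 by 6.87 on the mimic array. REG4 was lower by 6.52 on the Hep3B mimic array, with the outlying value on the control array. The limit of 5 that singled out these spots was set after the values had been seen.

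More genes were at least 2-fold different the same way in both lines (186) than in opposite ways (97). Noise of dim probes is argued against for genes well above background on all 4 arrays only. Among them 81 moved the same way and 11 opposite ways, and the lower bound of the share moving the same way was 79.6%. The rest of the 186 were dim on at least 1 array. The test did not cover them, and noise of dim probes stays open there. The largest difference among 8 spike-in probes was 0.14. An artefact of labelling or of the array that shifted most probes alike would be removed by the scaling of each array. It could not leave 2-fold differences at these 186 genes alone. The small spike-in differences therefore decide nothing about the cause of this pattern. With 8 probes, a shared artefact limited to few probes could not be seen and stays open. A shared biological response to the mimic, or to any transfected RNA that differs from the control in sequence, stays open, as does a shared position effect on gene probes that spike-ins would miss.

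Several gene lists were lower with the mimic. For a bias between arrays that depends on intensity, the test used quantile normalization. After it, 4 of the 7 lists called lower lay below the 2.5th percentile of expression-matched random lists in both lines. The same 4 lists lay there before it. Such a bias moves a list and its matched random lists together, so the normalization could hardly change this outcome and decides nothing. The place of these 4 lists below genes of like expression argues against such a bias as their whole cause. The other 3 lists (ribosomal proteins, histones and hepatocyte transcription factors) did not lie below the 2.5th percentile in both lines before that normalization either. The test could therefore not decide for them, and such a bias stays open. Their medians over the lines were -0.19, -0.15 and -0.15 before and -0.054, -0.12 and -0.16 after that normalization, so only that of the ribosomal proteins shrank much. A response of the cells to the mimic, including slower growth, was not tested.

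In Hep3B, IGF2 differed less at its brighter probe (-0.21 against -1.05), whereas its probes differed by much the same in HepG2 (-0.56 and -0.58). Compressed differences at very bright probes cannot be told apart from a real difference between the transcripts the probes measure: 3 of 3 genes with a probe as bright (100%) had the smaller difference at the bright probe, too few to decide. With the limit at 25% of that brightness, which was the first version computed and was not the limit written down, the share was 68.5% of 73 genes (exact 95% interval 56.6% to 78.9%). Absolute differences were compared, and noise alone can make them larger at a dimmer probe. Neither share can therefore show compression.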

How the results depend on the processing

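The filters by line, the probe sequence search and the adjustment for GC content were chosen after the data had been seen.

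No gene passed for the shared mimic effect under any of 10 alternatives in limma, with 104 genes (no block) to 2946 (intensity trend) at an unadjusted p under 0.05 against 1973. Line differences stayed between 9448 and 13116 genes under 9 alternatives against 9670, and 9 to 11 lists were called between the lines under 7. The authors' values and median scaling left every count, correlation and seed result within 1.5 times and on its side of the threshold. The cause of the changes below was not tested, except that a looser fold rule counts more genes and a stricter filter tests fewer. The normexp setting also adds an offset of 50, above the median probe signal of 22.4 to 27.5 per array. It thereby shrinks the log2 differences of dim probes by construction, and how much of its lower counts this makes was not tested.

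With normexp background correction, 571 genes were at least 2-fold different in Hep3B, 199 in HepG2 and 26 the same way in both, against 2033, 990 and 186; all 26 were among the 186. The correlation of the lines was 0.326, the effect differed at 595 genes, the seed-matched genes had a median of -0.059 with an unadjusted p of 0.0292 by camera, against 0.134, and ATGTACA ranked at 0.888%. With probes well above background on all 4 arrays, the counts were 848, 336 and 81, the correlation 0.335, the effect differed at 921 genes, and 7 lists lay outside random lists the same way in both lines, against 4. The seed median was -0.12, with an unadjusted camera p of 0.0163, and the rank 0.231%. With no filter, the counts were 5387, 4089 and 542, the correlation 0.0811, the effect differed at 7955 genes, 3473 genes differed between the lines, and the seed median was -0.10, with an unadjusted camera p of 0.0247. At 1.5-fold the counts were 4874, 2751 and 840. The rank of ATGTACA was 2.44% with the mean of all probes, 3.51% after adjustment for GC content and 6.81% with no filter. Camera called 4 lists after quantile normalization, against 8, and 0 with an estimated correlation; fry called 0.

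Camera's direction turned for lists that were called under no setting: the reported targets after quantile normalization (median -0.068) and with all 4 arrays (-0.061), the insulin-like growth factor axis (-0.034) and reference genes (0.063) after quantile normalization, inflammation genes with no filter (0.039), and markers of other cell types with all 4 arrays (-0.096). Of 141 named genes, 3 changed sign: GOLM1 with all 4 arrays (0.057), EMP1 with normexp (0.16) and MEG3 with the mean of all probes (0.068). Among 20 genes named for the line difference, TNS4 lost its call with no filter (adjusted p = 0.0567).

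Tests on the longest 3' UTR, 3' UTR length as a match for random lists and residuals on 3' UTR length were not run for lack of sequences. Leaving out 1 pair of arrays leaves no residual degree of freedom, so the counts have no such value. The single-line differences of named genes had the sign of the mean in 262 of 282 cases. By construction the larger difference of each gene has that sign, and some genes were chosen for moving the same way. The count therefore says little about stability.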

Other observations

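The gene families in the next paragraph and the genes named there were singled out after their values had been seen, and no test was run on them; the seed word test in the last one was written down before its outcome was seen.

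Annexins and S100 proteins, which bind calcium and pair with each other at membranes, lay high with the mimic in both lines. Of annexin genes well above background on both arrays of a line, 8 of 11 were higher in Hep3B and 7 of 10 in HepG2, or 6 of 10 in HepG2 after median scaling. The medians of all 12, dim readings included, were 0.30 and 0.18, at percentiles 99.9 and 99.5 of expression-matched random lists. Besides ANXA1, ANXA3 was higher by 1.38 and 2.56, whereas ANXA9 differed by -0.53 and -0.10. Of S100 genes, 9 of 12 were higher in Hep3B and 13 of 14 in HepG2. The medians of all 14, dim readings included, were 0.20 and 1.02, at percentile 98.9 and above all random lists; the Hep3B median was 0.075 after normexp background correction. S100A6 was higher by 1.14 and 2.93, S100A10 by 2.87 and 1.08, and S100A11 by 2.15 and 1.54, whereas S100P differed by -2.18 and -0.15. A family chosen for its values lies far out among random lists by construction, so these percentiles are descriptions.

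Direct action of the mimic through its seed is a candidate explanation of the lower median of genes with a seed match in a probe. It needed ATGTACA among the lowest 1% of 7-mers and a difference beyond 2 standard errors in both lines, and the word ranked at 5.64%, with differences of -0.08 (SE 0.07) in Hep3B and -0.05 (SE 0.04) in HepG2. The rank is neither low enough for that nor above 25%, the limit set for excluding it, so the question stays open. The rank met the 1% limit among probes well above background on all 4 arrays (0.231%) and after normexp background correction (0.888%), and not under the other settings. The words of miR-493-3p, miR-122-5p and the reverse complement of miR-493-5p, ranked for comparison, lay at 24.4%, 42.0% and 7.68%. A mimic is double-stranded, so the reverse complement may not be a neutral control. Adjusted for GC content, the reverse complement ranked at 3.84% and ATGTACA at 3.51%. In Hep3B the reverse complement ranked closer to the lowest than ATGTACA (12.2% and 12.4%; 5.26% and 7.42% adjusted for GC content), and in HepG2 miR-493-3p did (7.26% and 14.7%).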
